A study of Drosophila melanogaster with 3 samples.

How the data were processed

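The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of a tagged transcription regulator in whole embryos of Drosophila melanogaster collected from 0 to 24 h. Per the labels, the flies carried a fusion of CG11093, the gene now called fuss, to enhanced green fluorescent protein (eGFP), and the fusion was recovered with an antibody against GFP. Chromatin was sonicated and fragments of 200 to 800 bp were taken, per the labels' descriptions. There were 3 biological replicates of 1 group, with 1 technical replicate each, and replicate numbers were taken from the labels. The labels name a possible control experiment, which was not analysed here, so no comparison between groups was made.

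The sources analysed were 14 peak lists in dm6 coordinates. For each replicate the authors deposited a ranked list and a shorter thresholded list. How places came to enter the ranked lists is not given in the sources used here. The series as a whole has 4 ranked and 4 thresholded lists. Per the authors' file records, lists of the whole series drew on the alignments of all 3 samples and a control, while the records used here do not say which replicates entered which list. Irreproducible discovery rate (IDR) analysis gave the lists their names. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak is the authors' own and was used only to describe, rank or filter peaks within its list. The score column of the deposited lists tracks the global IDR. The ranked lists also give the −log10 of the global IDR, as deposited by the authors. The authors' q values, local IDR values and signal tracks were not used here. The remaining numeric column used, per the file headers and values an offset, places the summit inside each interval.

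Tested on the values, all 2388 peaks of the main list were rows of 1 ranked list with a global IDR at or under 0.01. That ranked list held 2446 such rows, of which 58 were left out of the thresholded list by a step that is not given in the sources used here. Each ranked list of the whole series has 8 further numeric columns, 32 in all, which hold values of inputs that no record names, and they were not used. Read depth is unknown, since the lists hold no read counts. The number of peaks is therefore the one measure of yield per library, and intervals given for shares cover counting error over peaks only.

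Coordinates are given 1-based on dm6. The reference was the Release 6 assembly with the Ensembl release 115 annotation (BDGP6 6.54). No interval on the 7 chromosome arms ran past the end of its arm in that reference. Peaks on other sequences were left out of every location test. Promoters were positions within 500 bp of any annotated TSS (transcription start site), including those of noncoding genes. Other classes followed in the order 5' UTR, coding exon, 3' UTR, intron and intergenic. Distances given for named genes run to the nearest TSS of a protein-coding gene, so a summit named by a distant gene can still be in the promoter class.

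The conservative thresholded list was chosen as the main list before the data were examined, as were the tests, 24 gene lists, 28 motifs and most alternatives. Sharing between lists was the share of summits inside an interval of the other list, set against 1000 circular shifts of the summits along each arm (one-sided permutation test). Promoter share was set against ranked peaks outside the main list with Fisher's exact test and against circular shifts, both two-sided. Arms were compared with exact binomial tests on arm length. Gene lists were compared with two-sided Fisher exact tests on genes with a summit within 1 kb of a TSS, among 13561 protein-coding genes with a ranked summit in that window. Motif matches within 50 bp of the summit were compared with a window centred 500 bp away in exact McNemar tests. GC content was compared between the same windows by 100000 sign flips, and signal with distance to the nearest TSS by 100000 permutations. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05. Peaks are not replicates, so these p-values describe the lists; spread between replicates is given as the SD of the value in each replicate's thresholded list.

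Named genes followed a fixed rule. The rule took fuss, the protein-coding gene with the nearest TSS for the 25 main-list peaks of highest signal found in all 3 replicates, up to 4 members of each gene list with a main-list summit within 1 kb, and the 3 genes with the most main-list peaks nearest to their TSS. The text names only part of the list members. Lists of markers stood for the cell types a whole embryo holds. Symbols in the lists were matched to the annotation, with 1 entry of the trachea list unmatched.

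The tests of gene lists, promoter share, replicate sharing, motifs, GC content, arms and strength were tested on simulated data, while the remaining feature classes, the divergent promoters, the strings of 8 bases and the fuss windows were not. Lists planted in 13968 simulated genes were found in 100% of draws, and 0.364% of the other lists were called. The planted lists were the ribosomal proteins (92 genes) and odorant receptors (56 genes), at a rate far above that of other genes. Smaller lists and weaker effects were not planted, so the power to find those is unknown. With 39.8% of 2351 simulated summits placed at TSSs beyond chance, 40.1% were recovered, and with 50.0% of summits planted in a second list, 50.1% were found there. Simulated GC differences were found in 100% of draws, and draws without one were called in 6.5%. A planted motif was found, along with 1 of the 27 others. Random draws had an arm called in 7% of cases. Planted relations of strength to location were found in 100% of draws, and 4% of draws without one were called.

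Alternatives covered the other lists of the series, a stricter IDR, the 1175 peaks with the higher signal, leaving out each replicate, other overlap rules and windows, other backgrounds and GC-matched controls. Leaving out a replicate kept the main-list peaks with a summit in a thresholded peak of both other replicates. The main list itself was not made anew, so these settings also select shared peaks. The nearest TSS setting also took all protein-coding genes as background. Alternatives added later were an IDR at or under 0.001, the strongest of each run of overlapping intervals, the 854 peaks found in all 3 replicates, random gene lists matched on the number of TSSs and the nearest TSS with the background of the main test. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Paired designs and splits of the samples do not apply to 1 group of 3.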

Results

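The tagged protein was fuss, a member of the Ski/Sno family of transcriptional co-regulators encoded on chromosome 4. The 3 replicates were libraries of whole embryos aged 0 to 24 h, and the cell types that gave the peaks were not tested. The thresholded lists held 1250 peaks in replicate 1, 1685 in replicate 2 and 2207 in replicate 3. The ranked lists behind them held 113153, 102607 and 116494 places. The main list of the series held 2388 peaks, of which 2351 lay on the 7 chromosome arms and covered 806 kb of 138 Mb. Its median peak was 384 bp wide. Signal values, which are the authors' own, ran from 2.04 to 2169 with a median of 145. Because 217 of the intervals overlapped a stronger one, the list stood for 2171 separate places.

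The first question was how far the replicates marked the same places. The strongest places were marked in every library, and the weak ones mostly were not. Of the main-list summits, 36.3% lay in a thresholded peak of all 3 replicates, against a mean of 0.165% after circular shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Replicate 3 covered 71.3% of the summits, replicate 2 covered 52.1% and replicate 1 covered 49.6%, while 20.8% lay in no replicate's thresholded peak. The main list drew on these libraries and is not independent of them.

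Compared with each other, the replicate lists overlapped far above chance in all 6 ordered pairs. The highest share was 85.7% of replicate 1 summits inside replicate 3 peaks, and the lowest was 50.2% of replicate 3 summits inside replicate 1 peaks. Shifted lists gave at most 1.37% in any pair, and every pair had an adjusted permutation p of 0.001, the smallest possible. Part of that range came from list length, since equal numbers of strongest peaks (1242 per replicate) gave shares from 67.1% to 73.8%. Across main-list peaks, the ranks of signal correlated between replicates 1 and 2 with a Spearman rho of 0.744, between replicates 1 and 3 with 0.766 and between replicates 2 and 3 with 0.743. Only peaks with a ranked peak in both replicates entered (2083, 2136 and 2090 in that order). Where several ranked intervals covered a summit, the highest signal was taken. These are correlations across peaks, which are not independent replicates. At the peaks of any replicate's thresholded list the mean rho was 0.669 ± 0.086 (SD over 3 pairs).

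The second question was where the protein was recovered relative to genes. With promoters taken as 500 bp from a TSS, they held the largest class of peaks, and coding sequence held almost none. A window of 200 bp gave a promoter share of 29.4%, under the 35.0% that introns held at 500 bp. Summits within 500 bp of a TSS numbered 1074, or 45.7% of the main list (95% Wilson interval 43.7 to 47.7%), and the replicate lists gave 48.9% ± 2.5 (SD, n = 3). Ranked peaks outside the main list were in promoters in 14.0% of cases (odds ratio 5.18, two-sided Fisher exact p = 4.0e-293), and circular shifts gave 13.5% on average and 16.9% at most. Coding exons held 1.57% of summits (0.599% ± 0.043 in the replicate lists, SD, n = 3), against 20.2% of ranked peaks and 13.7% of shifted summits (adjusted permutation p = 0.0024). Among main-list peaks shared by both other replicates, which is the setting without replicate 1, 2 or 3 (1105, 1059 and 897 peaks), the coding exon share was 0.271%, 0.0944% or 0.111%. It was 0.117% among the 854 peaks in all 3 replicates, so these values do not separate the omission from the choice of shared peaks. Introns held 35.0%, against 38.8% after shifts, and intergenic sequence held 16.8% against 28.7% (adjusted permutation p = 0.0024 for both). The intron share did not pass in the 2278-peak list of the series (36.2%). The 3' UTR share was 0.468% against 4.46% (adjusted permutation p = 0.0024), and the 5' UTR share of 0.553% did not differ from the shifted 0.778% (adjusted permutation p = 0.28).

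**Figure D1:**
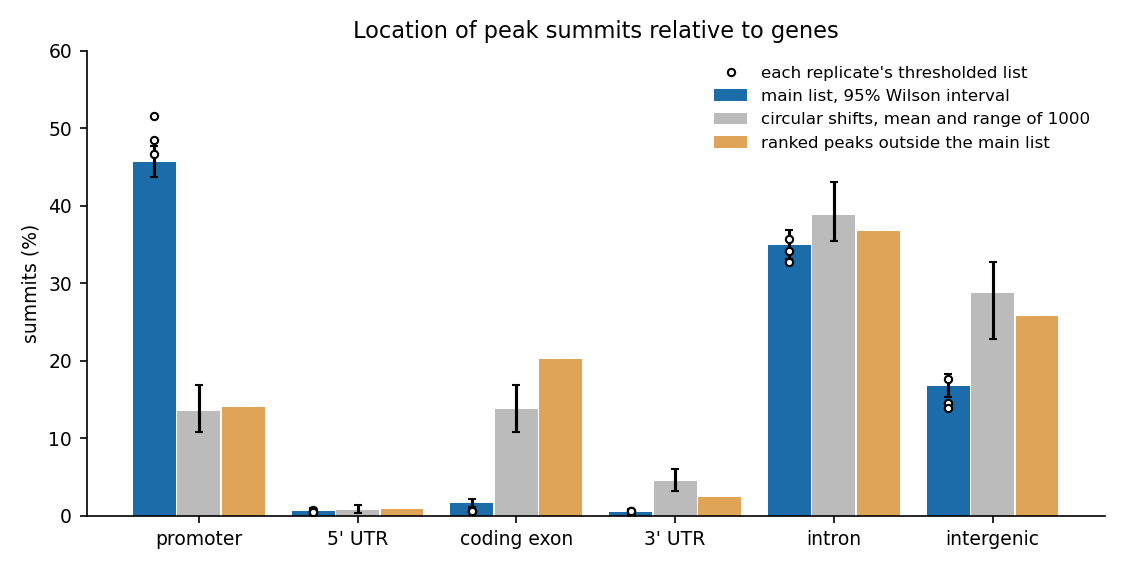
Share of summits (%) in each annotation class for the main list (blue bars, 95% Wilson intervals), circular shifts (grey bars, mean and range) and ranked peaks outside the main list (orange bars); open points are the thresholded lists of the 3 replicates. Promoters hold 45.7% of main-list summits against 13.5% after shifts, and coding exons hold 1.57% against 13.7%.

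Promoter summits sat upstream of the start site. Of the 1074, 80.7% were upstream of their nearest TSS, the median position was -131 bp, and 46.6% lay between 50 and 200 bp upstream. The intronic and intergenic remainder reached further, and 17.4% of all main-list summits were more than 5 kb from any TSS.

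The 25 strongest peaks found in all 3 replicates had this arrangement too. There were 18 in the promoter class, 5 in introns and 2 in intergenic sequence, and 13 lay within 200 bp upstream of a protein-coding TSS. The highest signal, 2169, was 23 bp upstream of Ugalt, a UDP-galactose transporter gene (FBgn0024994; chromosome X, 2703707 to 2704058). Its place ranked 1, 1 and 3 by signal in the ranked lists of replicates 1, 2 and 3. The next was inside an intron 784 bp downstream of the nearest TSS of Adf1, which encodes a DNA-binding activator (FBgn0284249; chromosome 2R, 6662877 to 6663252; signal 1952). The third was in an intron 1394 bp upstream of the nearest TSS of the zinc-finger gene cbt (FBgn0043364; chromosome 2L, 480913 to 481259; signal 1857).

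Peaks among the 25 were also found at ph-p, a Polycomb group gene (473 bp upstream, signal 1507), and at Chro, which encodes a chromodomain protein (88 bp downstream, signal 1486). An intronic peak was nearest to HmgZ, an HMG-box gene (557 bp upstream, signal 1625). Short upstream distances were seen at Tcs5 (110 bp), mRpL41, which encodes a mitochondrial ribosomal protein (138 bp), Art3, an arginine methyltransferase gene (115 bp), eIF6, a gene of ribosome biogenesis (104 bp), Atat, a tubulin acetyltransferase gene (124 bp), Fkbp14 (101 bp), CenG1A (92 bp), px (194 bp) and Sox14 (245 bp). The less characterised CG14100 (96 bp), CG7601 (102 bp), CG18549 (142 bp) and CG5611 (134 bp) had the same arrangement, and GstE13 had its peak 86 bp downstream. Peaks away from a coding start were nearest to tara (3176 bp upstream, intergenic), CG13323 (11914 bp, intergenic), CG11050 (1024 bp, intron) and CG32772 (1274 bp, intron). The peak nearest to CG4004, at 5072 bp, was within 500 bp of another annotated TSS. No place among the 25 ranked lower than 74 by signal in any replicate. Of the 25, 9 lay between a pair of protein-coding genes transcribed away from each other, with TSSs at most 1000 bp apart. These were the peaks named after Ugalt, CG7601, Chro, Tcs5, mRpL41, CenG1A, Art3, Atat and CG5611. Each of these names gives only the gene of the nearest TSS.

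The genes with the most main-list peaks nearest to their TSS were ATbp with 16, Ids with 10 and CG43245 with 9. None of the 16 peaks near ATbp, spread over 217 kb of the X (23216937 to 23434063), lay in a thresholded peak of all 3 replicates, and replicate 2 had no peak there in its ranked list. Near Ids (chromosome 3L, 3377863 to 3396407) 2 of 10 peaks were in all 3 replicates, and near CG43245 (chromosome 3L, 10738537 to 10784992) 3 of 9.

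The third question was whether strength went with location. The strongest peaks were nearer to start sites, lower in GC content and marked in more replicates. Across 4 groups of equal size by signal, from strongest to weakest, the promoter share went from 61.4% through 47.3% and 39.3% to 34.8%. The share lying in peaks of all 3 replicates went from 93.7% through 46.8% and 4.25% to 0.511%. Main-list signal and replicate lists come from the same libraries, so this fall is not independent evidence of reproducibility. Across the 2351 peaks, signal and distance to the nearest TSS had a Spearman rho of -0.20 (Pearson r of -0.14 on log2 values, two-sided permutation p = 1.0e-05 for rho, the smallest that 100000 permutations can give). Peaks are not independent replicates, and the relation is across peaks within 1 list.

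**Figure D2:**
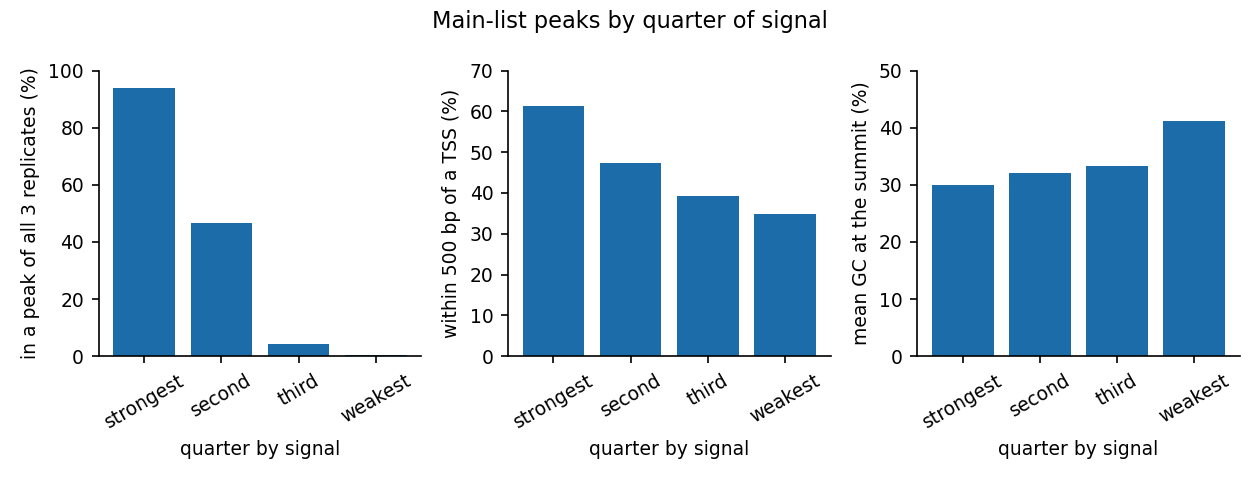
Main-list peaks in 4 groups of equal size by signal, from strongest to weakest: bars show the share lying in thresholded peaks of all 3 replicates (%), the share within 500 bp of a TSS (%) and the mean GC content within 50 bp of the summit (%). The share in all 3 replicates is 93.7% in the strongest group and 0.511% in the weakest, and mean GC is 29.98% and 41.2%.

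Base composition at the summits was the fourth comparison. Main-list summits were rich in A and T, and places that missed the threshold were not. Mean GC within 50 bp of the summit was 34.1% (SD 10.4 over peaks), against 43.8% (SD 10.03) in windows 500 bp away in the same regions. The mean difference was -9.72 percentage points, with the summit lower in 1759 of 2351 peaks (two-sided permutation p = 1.0e-05, the smallest possible). In the replicate lists the difference was -10.1 ± 1.7 (SD, n = 3), with the summit lower in each. A sample of 20000 ranked summits outside the main list had a mean GC of 46.5% (SD 9.6), above the 42.1% of the 7 arms together. Promoter summits averaged 32.3%, intronic ones 33.6% and intergenic ones 37.4%, while the 37 summits in coding exons averaged 59.0%.

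**Figure D3:**
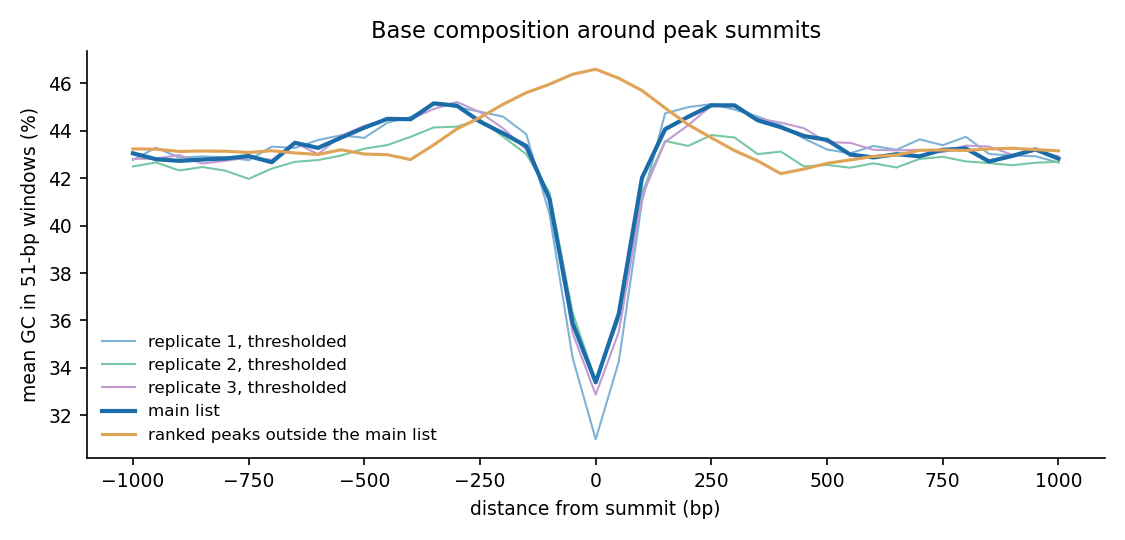
Mean GC content (%) in 51-bp windows against distance from the summit (bp) for the main list, the thresholded list of each replicate and ranked peaks outside the main list. The main list falls to 33.4% at the summit and the replicates to between 31.0 and 33.5%, whereas the ranked peaks rise to 46.6%.

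Of the 28 motifs, 2 were more frequent at summits than in flanks and 5 were less frequent. Matches to the TATA box were found at 8.04% of summits and 3.11% of flanks (adjusted exact McNemar p = 7.2e-12), with 8.37% ± 0.93 and 3.82% ± 0.35 in the replicate lists (SD, n = 3). The homeodomain core TAATTA was found at 9.91% and 6.25% (adjusted exact McNemar p = 4.7e-05). Lower shares at summits were found for the proneural E-box, CAGCTG (2.76% and 5.57%, adjusted exact p = 2.4e-05), the GAGA motif (0.893% and 2.47%, adjusted exact p = 2.6e-04), the Snail-type E-box (2.30% and 3.96%, adjusted exact p = 0.0067), the GC-rich site of the SMAD protein Mad (0.595% and 1.53%, adjusted exact p = 0.012) and the Pho core (2.17% and 3.49%, adjusted exact p = 0.034). The Pho core did not pass in the other 3 lists of the series, among the 1175 peaks of higher signal, or among peaks shared by any 2 replicates. The GAGA motif did not pass in windows of 100 bp on both sides (ratio to flanks 0.768), and the Snail-type E-box did not pass at an IDR at or under 0.001. The GAGA ratio was 0.362 in the main list, 0.125, 0.114 and 0.200 among peaks shared by both other replicates without replicates 1, 2 and 3, 0.143 among peaks in all 3 and 0.0789 among the peaks of higher signal. That of the proneural E-box was 0.496 in the main list, 0.288 among peaks shared by replicates 1 and 2 (without replicate 3) and 0.333 among peaks in all 3. The effect of a replicate was thus not separated from that of keeping shared peaks. The Su(H) motif passed as less frequent at summits among peaks shared without replicate 1 or 2, in the 1907-peak list, among the peaks of higher signal and at an IDR at or under 0.001. So did the CTCF core among peaks shared without replicate 2 and the Runt motif among peaks in all 3. The palindromic SMAD site was found at 2 summits and 2 flanks, and the Zelda motif at 31 of each. Against ranked summits of the same GC content, 0 motifs passed in Fisher exact tests (lowest adjusted p 0.062). Of the 28, 3 had an unadjusted p under 0.05, with Zelda and the CTCF core higher and the Hox-Exd site lower at main-list summits. TATA box matches were at 7.90% of main-list and 9.52% of matched summits, and the homeodomain core at 9.86% and 10.8%.

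The fifth comparison asked which groups of genes carried peaks within 1 kb of a TSS. Of 13561 background genes, 1514 did (11.2%). None of the 24 lists passed the adjusted threshold in Fisher exact tests, and 4 had an unadjusted p under 0.05. The lowest adjusted p was 0.12. It was shared by the chromatin insulator and Polycomb factors, where 8 of 28 genes had a peak (odds ratio 3.19, unadjusted Fisher exact p = 0.0095), and the heat shock genes, where 5 of 13 did (odds ratio 4.99, unadjusted Fisher exact p = 0.010). The former were led by ph-p and Chro and by Cp190, an insulator protein gene (115 bp upstream, signal 502), and E(z), the histone methyltransferase of the Polycomb system (55 bp downstream, signal 403). Among the latter, Hsp27 (163 bp upstream, signal 663), Hsc70-4 (205 bp) and Hsp26 (112 bp) had peaks of their own, while Hsp22 and CG4456 shared 1 peak. The summits at Hsp27, Hsp26, Hsp22 and CG4456 lay close together on chromosome 3L (9373600 to 9383900). The test counted these neighbouring genes as independent. Odorant receptors had a peak at 1 of 54 genes (Or88a; unadjusted Fisher exact p = 0.027) and epidermis and cuticle genes at 0 of 33 (unadjusted Fisher exact p = 0.046).

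These calls depended on the list taken. The insulator and Polycomb factors passed among the 1105 peaks shared by replicates 2 and 3, without replicate 1 (odds ratio 4.80), and among the 1175 peaks of higher signal (5.15), but not among those in all 3 replicates (3.88). The odds ratio of heat shock genes was 2.60, 2.65 and 5.19 among peaks shared without replicates 1, 2 and 3, and 3.23 in all 3. In the 1907-peak list it was 8.19, and heat shock genes passed there (adjusted Fisher exact p = 0.017). The odds ratio of odorant receptors was 0.150 in the main list, 0.269, 0 and 0 among peaks shared without replicates 1, 2 and 3, and 0 in all 3. In the 3560-peak list of the series, 4 lists passed: insulator and Polycomb factors, heat shock genes and ribosomal proteins were higher and odorant receptors lower. With each peak given to the gene of nearest TSS at any distance and all protein-coding genes as background, 7 passed. The BMP pathway, insulator and Polycomb factors, neuronal identity factors, neuroblast and temporal factors and segmentation genes were higher, and odorant receptors and histone genes lower. With the background of the main test, which was tried after seeing the data, 6 of these passed and the histone genes did not.

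None of the other 20 lists had an unadjusted Fisher exact p under 0.05. In the BMP and TGF-beta pathway, in which Ski/Sno proteins are known to act, 5 of 27 genes had a peak (unadjusted Fisher exact p = 0.22). They included Mad, the SMAD of the pathway (646 bp upstream, signal 373), nej (signal 266) and the repressor gene brk (767 bp upstream, signal 202), all in an interval marked in 3 replicates. Corepressors and histone deacetylases had 4 of 19, among them gro (135 bp upstream, signal 419) and ebi (139 bp upstream, signal 266). Ribosomal proteins had 15 of 90, led by RpL34b and RpL32, and the proteasome had 3 of 46. Proneural and Notch pathway genes had 4 of 34, led by numb (257 bp upstream, signal 460).

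Within 1 kb of a TSS, markers of cell types were hit in small numbers. Neuronal function had 1 of 37 genes, elav, a pan-neuronal RNA-binding protein gene (227 bp upstream, signal 545). Neuronal identity factors had 1 of 35 (lola), neuroblast and temporal factors 1 of 30 (brat) and gustatory receptors 1 of 36 (Gr32a). Glia had 3 of 17 with moody first (169 bp upstream, signal 546) and fat body 3 of 15 with Lpin first (signal 524). The midgut list had 3 of 20 with ver first, an entry whose role in the midgut was not checked. Muscle and mesoderm had 3 of 36, including the heart gene tin (199 bp upstream, signal 264). Germline and maternal genes had 2 of 18, segmentation genes 1 of 33 (bcd), the trachea 1 of 20 (trh), Hox genes 1 of 8 (Abd-B), and chorion and yolk genes 1 of 19. By nearest TSS at any distance, with the same background, 12 of 35 neuronal identity factors (odds ratio 3.72), 9 of 30 neuroblast and temporal factors (3.05) and 12 of 33 segmentation genes (4.08) had a peak. Those odds ratios were 0.234, 0.274 and 0.248 within 1 kb, so the direction depended on the assignment, and the space around these genes was not taken into account. Hemocyte markers (18 genes) and the 6 replication-dependent histone genes in the background had none.

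**Figure D4:**
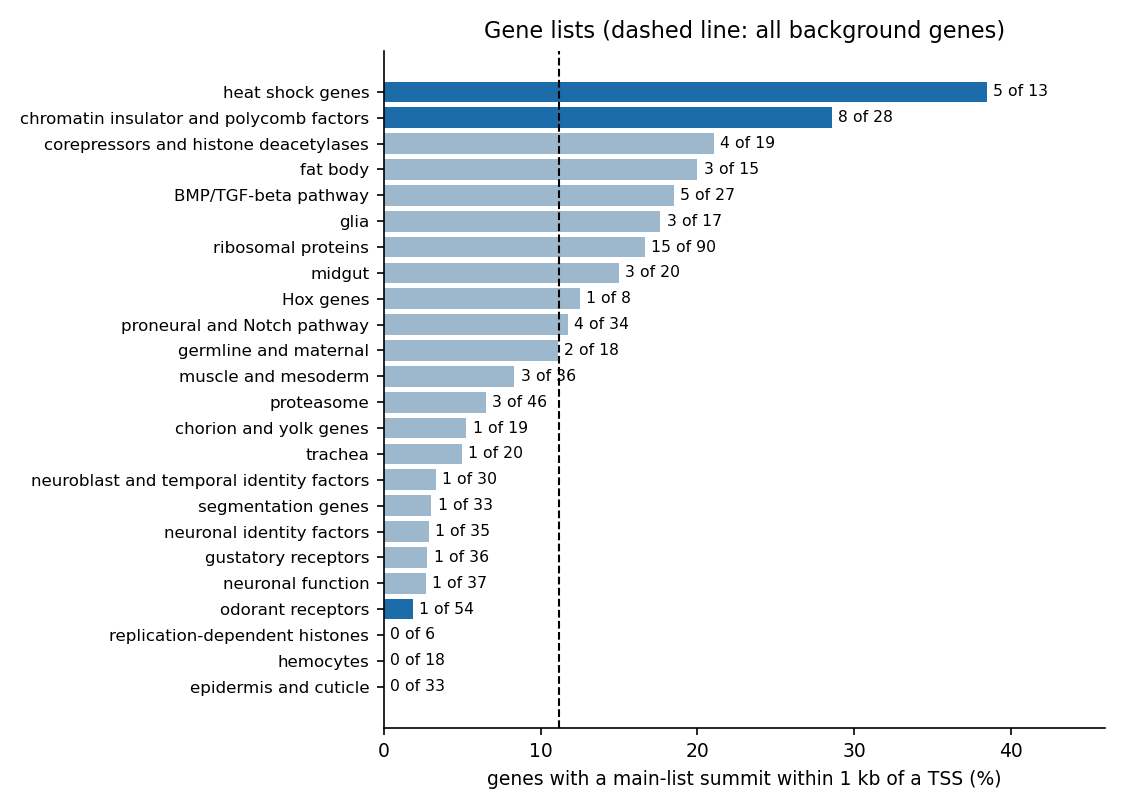
Share of the genes in each list with a main-list summit within 1 kb of a TSS (%), with the counts at each bar; the dashed line is the share over all background genes (11.2%) and dark bars have an unadjusted Fisher exact p under 0.05, while the adjusted threshold was not passed by any list. Heat shock genes (5 of 13) and insulator and Polycomb factors (8 of 28) have the highest shares.

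The last comparisons concerned chromosomes and the fuss gene itself. Peaks were more frequent than arm length gives on X and 2L, and rare on 4 and Y. X held 486 peaks (20.6 per Mb, 1.21 times the expectation, adjusted exact binomial p = 2.8e-05) and 2L held 464 (19.7 per Mb, 1.15 times, adjusted exact binomial p = 0.0014). In the thresholded lists of replicates 1, 2 and 3 the X ratio was 1.18, 1.06 and 1.26. The 2L ratio was 1.14, 1.18 and 1.05 in the same order, and no replicate was tested on its own. In the 3560-peak list the X ratio was 1.03 and no longer passed the threshold. Chromosome 4 held 5 peaks where length gives 23.0 (ratio 0.217, adjusted exact binomial p = 3.1e-05), and Y held 1 where it gives 62.7 (adjusted exact binomial p = 2.0e-25). By replicate, the thresholded lists held 1, 11 and 3 peaks on chromosome 4, where length gives 12.2, 16.5 and 21.1. Among main-list peaks shared by both other replicates, without replicate 1, 2 or 3, the ratio on chromosome 4 was 0.0923, 0.0963 or 0.114, against 0.119 among peaks in all 3, and Y held none. Ranked peaks were also few, at 115 against 1395 on chromosome 4 and 840 against 3794 on Y. Set against ranked peaks the chromosome 4 ratio turned to 2.63, without passing the threshold. The Y ratio stayed low at 0.0720 (adjusted exact binomial p = 2.4e-04). Arm length takes no account of the sex of the embryos, which the labels do not give and which bears on X and Y.

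One of the 5 peaks on chromosome 4 was found in all 3 replicates. It was 185 bp upstream of PlexA, an axon guidance receptor gene (1027200 to 1027371, signal 430). The other 4 lay between 1279111 and 1318406, with Cadps as the gene of nearest TSS at 47420 to 86332 bp. The peak on Y (2831060 to 2831443) was nearest to FDY, at 191037 bp. Among these intergenic peaks, only that at 1317189 to 1317572 lay in a thresholded peak of any replicate, namely 1. The ranked list of replicate 2 had no peak at any of them. These peaks were named after their values were seen.

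The fuss gene (FBgn0039932; chromosome 4, 962341 to 978489, minus strand) held no peak in any list, ranked lists included. Within 20 kb on both sides the main list and the lists of replicates 1 and 3 were empty as well. Replicate 2 had 2 thresholded peaks there, with summits at 982910, upstream of the gene (signal 105), and at 960414, beyond its 3' end (signal 68.8). Random windows of the same length on chromosome 4 held a mean of 1.41 ranked peaks of the main list's parent, so that 0 peaks in fuss stood at the 37.9th percentile, and at the 11.1th in replicate 2. At this density of ranked peaks a lack of binding at the gene was not detectable.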

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

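The comparison of sequences outside the arms was chosen after the data were seen. Peaks outside the 7 chromosome arms entered no location test, and the main list held 37 of them on 32 unlocalised sequences of the X, with signal values up to 208. By replicate, the thresholded lists held 8 such peaks in replicate 1, 0 in replicate 2 and 58 in replicate 3. The region of the X nearest to ATbp (23216937 to 23434063) held 3, 0 and 22 thresholded peaks in the same order, and 83, 0 and 180 ranked ones. Of the other lists of the series, those of 1907 and 2278 peaks had none in either place, and that of 3560 peaks had 31 and 11. The number of replicates is too small for a test of this difference, and no explanation was tested.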

How the results depend on the processing

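The settings with an IDR at or under 0.001, the strongest of overlapping intervals, the peaks in all 3 replicates, random lists matched on TSS number and nearest TSS with the main background were chosen after seeing the data. An IDR at or under 0.01 removed no peak and says nothing about stability. Replicate sharing, pair sharing, promoter and coding exon share, GC content and the relation of strength to location kept their direction and side of the threshold in each alternative run. The intron share lost its threshold in the 2278-peak list, and X in the 3560-peak list. The number of arms past the threshold was 4 in the main list, 5 among peaks shared without replicate 1 and 5 against ranked peaks, where 2R and 3R passed and chromosome 4 did not. Promoter share ranged from 29.4% (200 bp window) to 56.4%, coding exon share from 0.0866% to 4.14%, and the GC difference from -13.2 to -6.89 percentage points. The relation of signal to distance ranged from -0.24 to -0.13. Main-list peaks shared by both other replicates, the settings without replicate 1, 2 or 3, gave promoter shares of 52.7% to 55.4%, coding exon shares of 0.0944% to 0.271%, chromosome 4 ratios of 0.0923 to 0.114 and made up 38.2% to 47.0% of the main list. Peaks in all 3 replicates gave 55.9%, 0.117% and 0.119, so these shifts cannot be put down to the omission of a replicate.

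The calls of gene lists did not hold. None passed in the main list, 1 in the list of 1907 peaks (heat shock genes) and 1 in that of 2278 (insulator and Polycomb factors). The list of 3560 peaks gave 4 and the 1175 peaks of higher signal gave 1. Among peaks shared without a replicate 0 to 1 passed (1 without replicate 1, the insulator and Polycomb factors). A 5 kb window gave 2 and all protein-coding genes as background gave 1. By nearest TSS 7 passed with that wider background and 6 with the main one. The wider background adds histone genes without a ranked summit, and otherwise the cause was not tested. The insulator and Polycomb odds ratio ranged from 3.07 to 5.15, that of heat shock genes from 2.33 to 8.19 and that of odorant receptors from 0 to 0.269.

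With GC-matched ranked summits 0 motifs passed, and the ratios of TATA box and homeodomain matches turned to 0.830 and 0.909; this setting changed the control windows as well as their GC content, and the cause was not tested further. On chromosome 4 the ratio turned to 2.63 against ranked peaks, which are few there. With 50 kb on both sides, 1 main-list peak fell in the fuss region. Mean rank agreement went from 0.751 to 0.669 over peaks of any replicate, and the cause was not tested. No paired analysis was possible because there is 1 group.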

Other observations

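The tests of weak intervals as the cause of AT-rich summits, of passing rates by GC within each class, of reproducibility taken over from a neighbour and of the threshold on chromosome 4 were chosen only after their results were seen, as was the comparison of signal that left the test of separate weaker sites open.

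Many promoter peaks lay between a pair of genes transcribed away from each other. Of the 1074 promoter summits, 398 (37.1%) were between divergent protein-coding TSSs at most 1000 bp apart, and the replicate lists gave 36.3% ± 4.0 (SD, n = 3). Among ranked promoter summits outside the main list the share was 5.90% (odds ratio 9.38, two-sided Fisher exact p = 5.0e-182), a ratio of 6.28. Since main-list summits sit upstream, positions at the same distances from random protein-coding TSSs were taken as a second background, and 20.4% of them (95% Wilson interval 19.6 to 21.2%) lay between divergent TSSs, a ratio of 1.82. Neither background reached the observed share. The second drew TSSs and not genes, so genes with many TSSs weighed more, and a draw by gene was not tested. The upstream position is therefore not excluded as the cause. The activity of these promoters was not tested.

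Several developmental regulators collected runs of peaks mostly outside promoters, and these genes were picked after their values were seen. Near shn, a zinc-finger cofactor of SMAD proteins, 8 peaks spanned 28.5 kb of chromosome 2R, with 3 in all replicates and none in a promoter. Near sbb, 7 peaks spanned 22.4 kb with 5 in all replicates and 1 in a promoter, and near tara 7 peaks spanned 26.3 kb with 4 in all replicates and 0 in a promoter. CHES-1-like had 8, of which 2 were in promoters, and the nuclear receptor gene Hr4 had 7 with 0 in promoters, with 3 in all replicates at each.

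AT-rich summits cannot be told apart from a base composition bias of the libraries or the control, and the design, with 1 group, tests no biological explanation. Among ranked summits with 32% GC or less, 25.6% passed in promoters and 5.59% elsewhere, a ratio of 4.57, but this does not bear on bias as it was meant to, because summits of low GC passed 10.2 times as often as others in promoters and 8.55 times as often elsewhere, and such a like dependence is what a bias would give. Genes without a peak were less AT-rich at the same offsets, by 7.70 percentage points of GC (40.0% against 32.3%). They were chosen for lacking a peak, which a bias towards low GC would also select for, so this does not describe promoters as such. Leaving out overlapping weaker intervals made the difference between summit and flank larger (1.10 times). The TATA box and homeodomain matches may follow from base composition, as their ratio to GC-matched summits was 0.909 at most. Strings of 8 bases leave open whether base composition alone is the cause, since the 5 most enriched on 2L, 2R and 3L had a median ratio of 1.33 to GC-matched summits on the other arms, with 0 of the 5 past the adjusted Fisher exact threshold and 0 with an unadjusted p under 0.05.

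Weak intervals beside strong peaks made up part of the main list. On the 7 arms, 213 intervals overlapped a stronger one and had a median signal of 13.9, against 157 for single intervals. A replicate summit lay within 50 bp of 9.39% of these intervals and of 79.9% of single ones (95% Wilson intervals 6.16 to 14.1% and 78.0 to 81.6%). Separate weaker binding sites stay open, because the main list held too few single intervals of such low signal to compare at matched strength. Whether such an interval took over the reproducibility of the peak it overlaps stays open too. Of these intervals, 87.8% had a signal below the 1st percentile of single ones (63.3), but low signal is part of how they were singled out and would be seen with separate weak sites as well. How the authors' IDR step paired intervals is not given in the sources used here.

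The shortage of peaks on chromosome 4 was already there in the ranked list, before the threshold. Whether it arose in the calling or in an earlier selection of the ranked places was not tested. Ranked peaks were already at 0.0825 of the number its length predicts, and AT-rich windows are not scarce there, at 1.95 times the mean density of the other arms. Replicate 2 stood apart with 478 ranked peaks on chromosome 4, against 137 in replicate 1 and 106 in replicate 3. An extra tagged copy of the fuss region was predicted to gather them near the gene. Of these ranked peaks 6.28% lay within 50 kb of fuss, where 8.62% of the chromosome's length lies, so as a whole they did not gather there. Of the 11 thresholded peaks of replicate 2 on chromosome 4, 4 lay within 50 kb of fuss. In replicate 1 it was 1 of 1 and in replicate 3 it was 1 of 3, so such peaks were not particular to replicate 2. That count was not part of the prediction and cannot decide it. The count of ranked peaks takes no account of their strength, so an extra copy was not excluded. Different coverage of chromosome 4 in the control or between libraries was not tested.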
